A study of Mus musculus with 4 samples.

How the data were processed

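RNA was prepared with Trizol and a Qiagen kit from untreated YAMC cells and from cells given LGG conditioned medium for 16 h, per the labels, and was profiled on 4 mouse 430A arrays. The authors deposited 1 table of linear intensity values, 1 column per array, with software, scaling and filters not given in the sources used here. The values lay between 0.1 and 19844, were never negative and had trimmed means, without the lowest and highest 2%, of 513.5 and 500.1 on the untreated arrays and 506.1 and 500.1 on the treated arrays, so each array appears scaled to a common mean. No detection calls or scanner images were used here, so a bound against background cannot be given for dim probe sets. Both arrays of date 1 had no value for the same 6307 probe sets, of 22690 in the table, which is a step the labels do not describe. These probe sets were left out of the comparison of the groups, and the values at date 2 were looked at separately.

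The group of each array came from its title. The titles give no replicate numbers, but they give 2 dates, each shared by 1 untreated and 1 treated array, so the dates pair the arrays and the fit had the date as a block. What the dates mark (culture, hybridisation or scan) is not given. As a check of the pairing, the difference between the dates in the untreated arrays correlated at 0.27, across probe sets, with that in the treated arrays, and 27 genes differed between the dates in the same fit. The groups, the tests, the rule for named genes, 29 gene lists and the alternatives were fixed before the data were examined.

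The trimmed means differed by under 5%, so the values were used as deposited. The pseudocount was 25.2 (5% of the geometric mean of the trimmed means, 504.9) and values were taken as log2(intensity + 25.2), a scale on which the fold of a dim gene is understated. After 64 control probe sets were set aside, 16319 probe sets had values on all arrays, and the 10333 with a mean of at least 101 (20% of the trimmed mean) were tested. Names came from the platform annotation provided with the table. Of the 22690 probe sets, 20393 had 1 gene symbol, 691 several and 1606 none. Of those with 1 symbol, 20364 matched the mouse RefSeq gene table of assembly GRCm38.p6 by Entrez identifier, which changed 0 symbols. Of the probe sets tested, 9594 had 1 symbol, 296 several and 443 none, and no gene was named from a probe set with several. No genome build is named for the array, so no coordinates are given. A gene was represented by its brightest probe set, which gave 6952 genes. Of the 452 genes called, 162 had several probe sets and 18 had probe sets of opposite sign: Hspa4, Cav2, Srp9, Rab2a, Notch1, Dcbld1, Leprotl1, Trip12, Kif1b, Dyrk1a, Dlat, Smc5, Ncam1, Nfib, Polr1d, Wwc2, Med1 and Hs2st1.

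Tests used limma 3.58.1 in R 4.3.3: lmFit with group and date, eBayes with an intensity trend, and Benjamini-Hochberg adjustment over all probe sets tested, with a threshold of 0.05. With the block the fit had 1 residual degree of freedom per probe set and 12.5 prior degrees of freedom, and without it 2 and 6.25, so the called genes rest on the variance that limma shares across genes. Gene lists with at least 5 members tested were compared with other genes by camera with the preset correlation of 0.01 and again with an estimated correlation. The estimated form rests on 1 residual degree of freedom here and could hardly pass any list, so its p-values decide little. The fry test, which compares a list with no change and not with other genes, was also run. All were two-sided and adjusted over the lists tested. A list's members were also adjusted over the list alone. The pattern for ribosomal protein genes also took the Rps6k kinases, which were removed after the table was seen. Genes at least 2-fold changed at both dates were counted from the ratio within each date, with no test. The text names, in each direction, up to 15 genes with the largest fitted change among those that passed with the same sign at both dates; of each list, up to 4 members with the largest change of the same sign at both dates, passed or not; and Hspa1a, Hspa1b and Hspb1 always. Any other gene in the text, such as Hspa8, Ptprc, further members of a list that passed and the cell type markers, was chosen after its values were seen. Figures were drawn with matplotlib 3.10.9.

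The fit was tested on simulated data for this comparison, with 10333 probe sets for 6952 genes, in 20 runs per setting. Of the genes, 200 were changed 2-fold or 4-fold and 20 more formed a list with a smaller shift. Calls of genes in that list were kept among the calls and not counted as false. With the date as a block and a true prior of 12 degrees of freedom, 61.6% of the 2-fold and 99.6% of the 4-fold changes were recovered, 0 with the wrong sign, and 7.71% of the calls were false, above the nominal 5%. With a true prior of 4, these shares were 5.75%, 55.5% and 7.19%. Without the block they were 22.1%, 97.6% and 0.91% at 12, and 1.15%, 64.9% and 2.44% at 4. The simulated list, shifted by 0.5 on the log2 scale, was called in 100% of the runs and an unchanged list in 0%. These calls were by camera with the preset correlation, at an unadjusted p under 0.05. The simulated genes varied independently, so this does not test camera for lists whose genes vary together.

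Alternatives were no date block, each array left out in turn (without the block, since 3 arrays leave no residual degrees of freedom with it), pseudocounts of 1% and 20%, quantile normalization, median scaling, no filter and a filter at 50%, eBayes without a trend and with a robust trend, an adjusted p under 0.10, probe sets in place of genes, 1.5-fold in place of 2-fold, and for the lists an estimated correlation, fry and the mean of all probe sets of a gene. Probe sets that can bind several transcripts, the Rps6k kinases and the correlation of the dates under other settings were added after the data were seen.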

Results

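Gene expression was measured in YAMC cells, a conditionally immortalised line of colon epithelial cells from young adult mice. The cells were either left untreated or kept for 16 h with medium conditioned by Lactobacillus GG (LGG), a probiotic strain of intestinal bacteria. Total RNA was hybridised to 4 mouse 430A arrays, 2 per group, and the array titles place 1 untreated and 1 treated array at each of 2 dates, called date 1 and date 2 here. Nothing in the labels says that the arrays came from separate cultures, so the spread between them may be technical. The limma p-value and SE of a gene rest mostly on variance shared across genes (12.5 prior degrees of freedom against 1 residual). They can therefore understate how far the dates differed for that gene, and they do not measure spread between cultures. The table held linear intensities for 22690 probe sets. Both arrays of date 1 had no value for the same 6307 probe sets, and these were left out of every comparison of the groups. The mean intensity of an array, without its lowest and highest 2% of values, lay between 500.1 and 513.5. After dim probe sets were left out, 10333 probe sets for 6952 genes were compared, and the number of arrays limits the precision of each value. On the log2 scale, the intensities of these probe sets correlated at 0.970 between the untreated arrays, 0.946 between the treated arrays, 0.940 between the groups at date 1 and 0.931 between the groups at date 2.

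The comparison of treated with untreated cells asks which transcripts differ in YAMC cells kept in LGG conditioned medium. Cells given unconditioned or acidified medium were not analysed here, so for no gene can products of LGG be parted from effects of acid, lactate or the medium itself. The 2 largest fitted changes were those of inducible Hsp70 genes. Hspa1b, which encodes an inducible Hsp70 chaperone, rose from an intensity of 267 ± 0.0707 to 5891 ± 3854 (SD, n = 2 arrays per group), a log2 change of 4.17 ± 0.28 (SE; limma, adjusted p = 4.74e-06). Hspa1a, its close paralog, rose from 28.4 ± 1.27 to 1079 ± 975, a log2 change of 4.01 ± 0.39 (adjusted p = 0.000186). Hspb1, the small heat shock protein known as Hsp25 in the mouse, rose from 1123 ± 31.7 to 8310 ± 5527, a log2 change of 2.68 ± 0.26 (adjusted p = 0.000186). The rise was seen at each date and was larger at date 1, with log2 ratios at dates 1 and 2 of 4.89 and 3.45 for Hspa1b, 5.09 and 2.93 for Hspa1a, and 3.44 and 1.92 for Hspb1. Without LGG replicate 1 the log2 changes of Hspa1b, Hspa1a and Hspb1 were 3.45, 2.95 and 1.95, and without LGG replicate 2 they were 4.89, 5.06 and 3.42. The other probe sets of these genes moved the same way, with log2 changes of 4.43 and 3.92 for Hspa1b and 3.32 for Hspb1. Hspa1a and Hspa1b are nearly identical in sequence, so the share of the signal that belongs to each is uncertain. Fold changes were computed on log2(intensity + 25.2) and understate the change of dim genes such as Hspa1a.

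Over all genes tested, 209 rose and 243 fell after LGG conditioned medium (limma with date as a block, Benjamini-Hochberg adjusted p under 0.05). The fitted change was at least 2-fold for 106 of those that rose and 134 of those that fell. All 452 had the same sign at both dates, against 65.2% of all genes tested. The call all but requires this, since a difference between the dates counts as noise in the fit. It is therefore no measure of how well the dates agreed. The median log2 change of all genes was 0.03. Taken date by date, 47 genes were at least 2-fold higher at both dates, 71 were at least 2-fold lower at both dates and 0 were 2-fold changed in opposite directions, a count without a test. Without date as a block 24 genes rose and 37 fell, all among the 452, and in fits without the block limma called 0 genes when untreated replicate 1 or untreated replicate 2 was left out (485 and 533 genes at an unadjusted p under 0.05, against 1064 with all arrays and no block), 198 higher and 230 lower without LGG replicate 1 (284 of the 428 among the 452) and 74 higher and 113 lower without LGG replicate 2 (159 of the 187). With no filter on dim probe sets 0 of 10782 genes passed, against 1525 at an unadjusted p under 0.05, and a permutation of 2 against 2 arrays cannot give a two-sided p under 0.333.

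**Figure D1:**
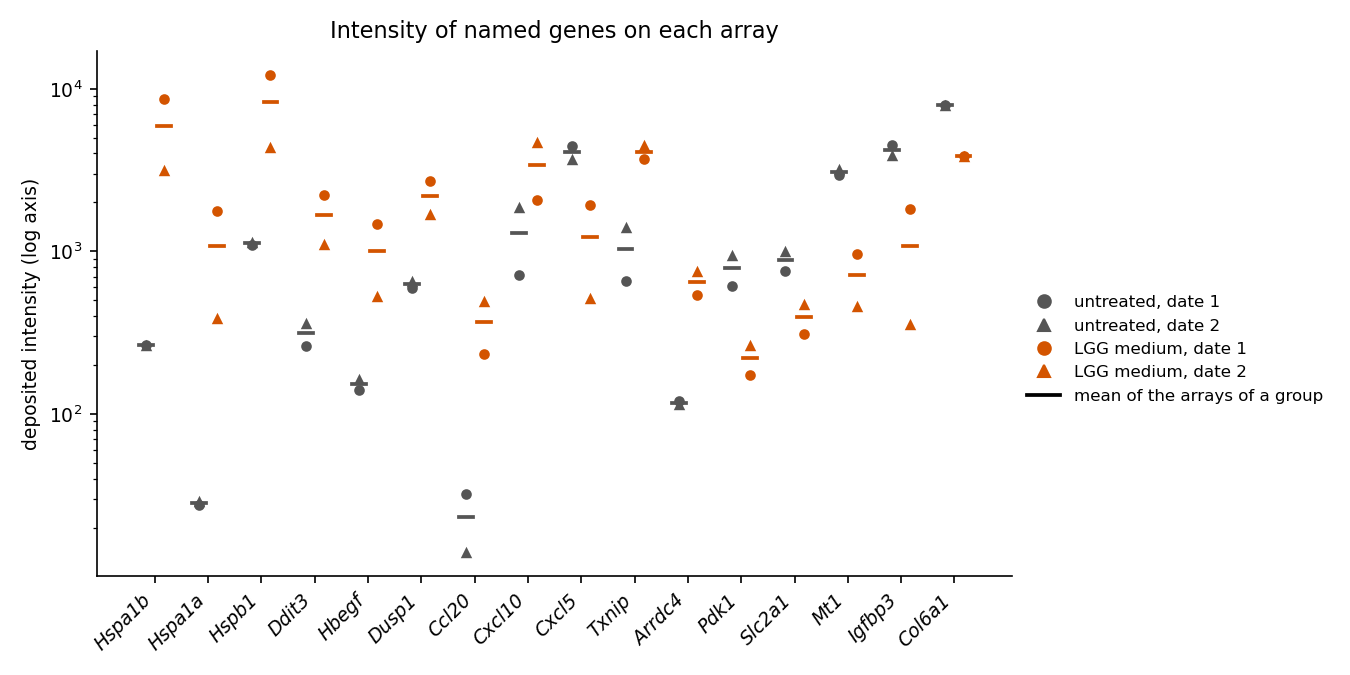
Deposited intensity (log axis, arbitrary units) of 16 named genes on each of the 4 arrays, with circles for date 1, triangles for date 2, grey for untreated cells, orange for LGG conditioned medium and short bars for the mean of the 2 arrays of a group. Hspa1b lies near 267 on both untreated arrays and at 8617 and 3166 on the treated arrays, and Col6a1 falls from a mean of 7996 to 3841.

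The other genes with the largest rises covered secreted factors, stress regulators and 2 arrestins. Ccl20, a chemokine that attracts dendritic cells and lymphocytes, rose from 23.3 ± 12.9 to 366 ± 186 (log2 change 2.95 ± 0.35, adjusted p = 0.000453). Hbegf, an EGF receptor ligand, rose from 152 ± 15.5 to 1008 ± 671 (2.37 ± 0.32, adjusted p = 0.000858). The arrestins Txnip and Arrdc4, which limit glucose uptake, had log2 changes of 2.05 ± 0.21 and 2.23 ± 0.25 (adjusted p = 0.000187 and 0.000397). Ddit3, a stress transcription factor also called CHOP, had a log2 change of 2.26 ± 0.29, Gadd45a, a growth arrest and DNA damage gene, 1.92 ± 0.25, and Ccn2, a matricellular protein, 1.78 ± 0.17. Pacsin3, which takes part in endocytosis, had a log2 change of 2.15 ± 0.29, the class I histocompatibility gene H2-Q5 2.10 ± 0.28 and Hid1 2.04 ± 0.27. The kinase gene Sgk1 (1.97 ± 0.35) and the small GTPase gene Rab3b (1.96 ± 0.42) passed with date as a block but not without it (adjusted p = 0.0771 and 0.197). Rab3b measured 55.1 on the untreated array of date 1 and 413.7 on that of date 2, and its log2 change was 0.74 without untreated replicate 1 and 3.19 without untreated replicate 2. Sgk1 measured 834.7 and 300.8 on the treated arrays, and its log2 change was 1.28 without LGG replicate 1 (adjusted p = 0.053) and 2.67 without LGG replicate 2. Without LGG replicate 1 the log2 changes of Hbegf and Ddit3 were 1.66 and 1.77, and without LGG replicate 2 they were 3.09 and 2.74.

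The 15 genes with the largest falls decreased 3.38-fold to 6.12-fold. Angptl7, an angiopoietin-like secreted protein, fell from 416 ± 3.61 to 50.2 ± 31.2 (log2 change -2.61 ± 0.29, adjusted p = 0.000362). Igfbp3, which binds insulin-like growth factors, fell from 4208 ± 430 to 1086 ± 1033 (-2.33 ± 0.33, adjusted p = 0.0013), with log2 ratios of -1.30 at date 1 and -3.37 at date 2. Efnb2, a membrane ligand of Eph receptors, fell from 1785 ± 82.2 to 389 ± 159 (-2.18 ± 0.23, adjusted p = 0.000307). Cxcl5, a neutrophil chemokine, fell 3.99-fold, from 4096 ± 538 to 1218 ± 991 (adjusted p = 0.00105). The metallothionein gene Mt1 had a log2 change of -2.16 ± 0.25 and Smpd3, a neutral sphingomyelinase gene, -1.90 ± 0.22. The remaining genes of this set were Sytl1 (-2.48), Ppp2r2b (-2.45), Medag (-2.21), Trib1 (-1.93), Steap4 (-1.90), Tnmd (-1.87), Cemip (-1.81), Plce1 (-1.76) and Ddc (-1.76). Without date as a block the calls of Igfbp3 (adjusted p = 0.108), Cxcl5 (0.105), Tnmd (0.056), Cemip (0.123), Plce1 (0.0509) and Ddc (0.0771) were lost. Without LGG replicate 1 the log2 changes of Igfbp3, Cxcl5, Ppp2r2b and Cemip were -3.47, -2.92, -3.17 and -1.17, and without LGG replicate 2 they were -1.20, -1.08, -1.73 and -2.45.

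**Figure D2:**
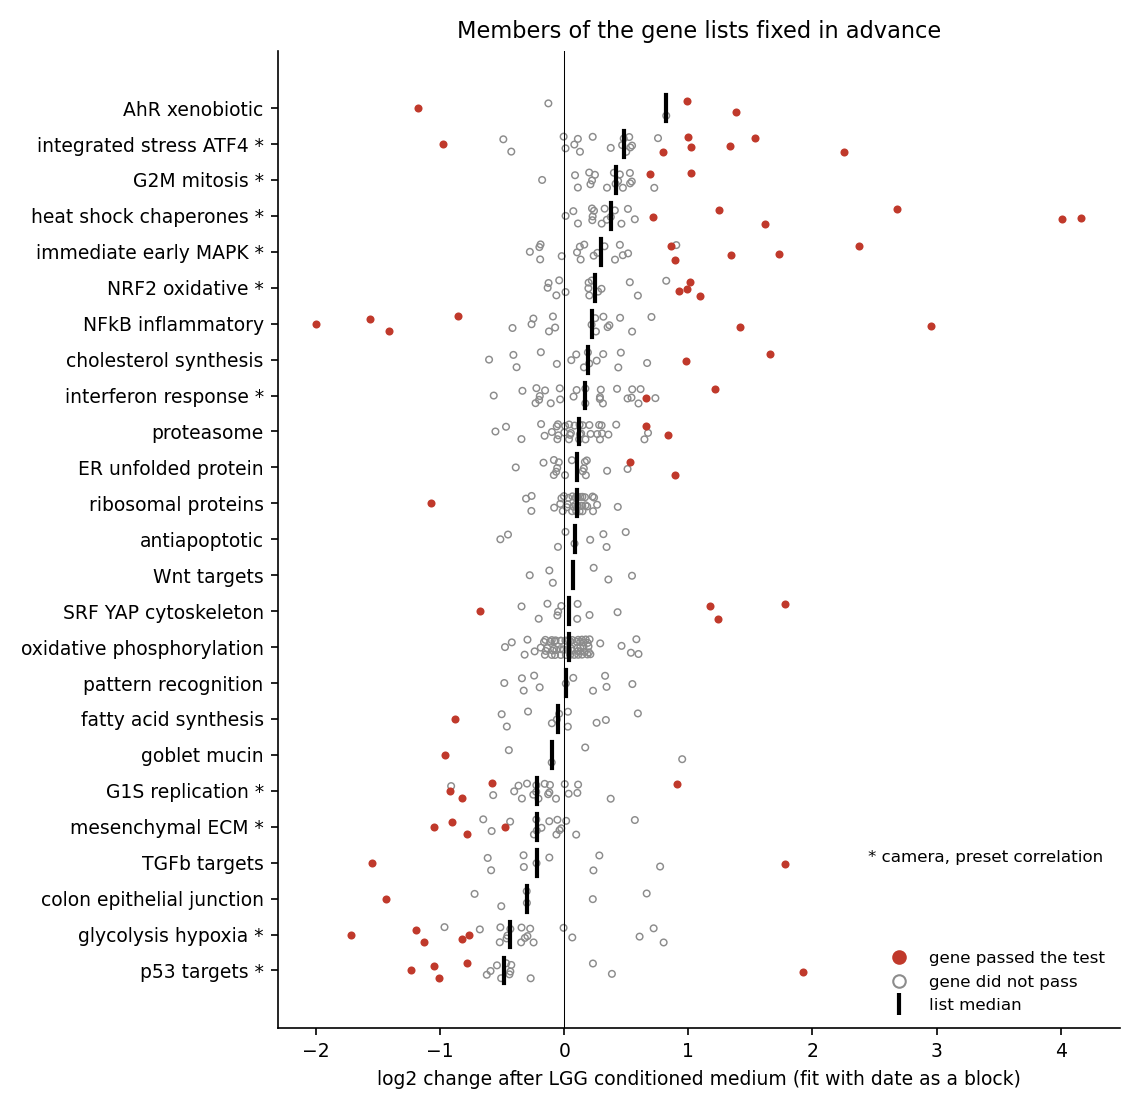
Log2 change after LGG conditioned medium (x axis, fit with date as a block) of the members of the 25 gene lists with at least 5 genes tested, 1 row per list, with red points for genes that passed, open points for genes that did not, black bars for list medians and a star for lists that passed camera with the preset correlation. Medians run from -0.49 for p53 targets to 0.82 for the 5 aryl hydrocarbon receptor genes, and Hspa1b and Hspa1a lie near 4 in the heat shock row.

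Of 21 heat shock and chaperone genes tested, 6 rose and 0 fell, against 7 and 0 when adjusted over the list alone. Beside the 3 genes already given, Hspa4l rose by a log2 change of 1.62 ± 0.24 and Hsph1, an Hsp110 chaperone, rose from 2156 to 5486 (1.25). Hspa4 rose too (0.71), but its probe sets disagree in sign. Hspa8, the constitutive Hsp70, measured 8032 and 8720 (log2 change 0.11, adjusted p = 0.682). The list median was 0.37 (0.54 at date 1 and 0.25 at date 2), higher than other genes by camera (adjusted p = 5.69e-09; adjusted p = 0.669 with an estimated correlation). Of 23 genes of the integrated stress response, 6 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.48, or 0.43 at date 1 and 0.42 at date 2 (adjusted p = 0.000114; adjusted p = 0.669 with an estimated correlation). Beside Ddit3 these were Ppp1r15a, a phosphatase subunit that restores translation (1.54 ± 0.31), the transcription factor gene Atf3 (1.34 ± 0.36), Nupr1 (1.02 ± 0.24), Trib3 (0.99) and Slc3a2 (0.79), while Cebpb fell (-0.98). Without LGG replicate 1 the log2 changes of Ppp1r15a and Atf3 were 0.68 and 0.42, and without LGG replicate 2 they were 2.40 and 2.25. Trib3 had log2 ratios of 1.39 at date 1 and 0.60 at date 2, and Trib3, Slc3a2 and Cebpb were not refitted with an array left out. Of 18 genes of the unfolded protein response in the endoplasmic reticulum, 2 rose, Herpud1 (0.89 ± 0.19) and the chaperone gene Hspa5 (0.53 ± 0.10), and 0 fell, 2 and 0 adjusted over the list alone. The list did not pass (median 0.10, adjusted p = 0.229), and Edem1 (0.51) and Sec61b (-0.39) did not pass singly. Without date as a block, 4 heat shock genes (Hspa1b, Hspa1a, Hspb1 and Hspa4l), 1 gene of the integrated stress response (Ddit3) and 0 of the unfolded protein list passed.

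Of 22 immediate early genes and feedback regulators of MAP kinases tested, 5 rose, 0 fell and 17 did not pass, the same counts adjusted over the list alone. Those that rose were Hbegf, the MAP kinase phosphatase gene Dusp1 (from 628 ± 40.4 to 2199 ± 701, log2 change 1.73 ± 0.23), Maff (1.34 ± 0.34), Ier3 (0.89) and Phlda1 (0.86). Phlda1 had log2 ratios of 1.24 at date 1 and 0.48 at date 2, and Ier3 and Phlda1 were not refitted with an array left out. Fosl1, a Fos family gene, had a log2 change of 0.90 ± 0.33 and did not pass (adjusted p = 0.131). The list passed camera (adjusted p = 0.00174; adjusted p = 0.669 with an estimated correlation), but its median was 0.78 at date 1 and -0.07 at date 2, and without LGG replicate 1, the treated array of date 1, its mean was -0.00365 and its adjusted p 0.708. Without LGG replicate 1 the log2 change of Maff was 0.51 and without LGG replicate 2 it was 2.17. Without date as a block, Hbegf and Dusp1 passed. The ratio of 3' to 5' signal of Gapdh, a measure of RNA integrity, went from 0.805 to 0.931 with treatment at date 1 and from 0.784 to 0.768 at date 2.

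Inflammatory genes moved in both directions. Of 21 targets of NF-kappaB tested, 2 rose and 4 fell (3 and 4 adjusted over the list alone), and the list did not pass (median 0.22, mean 0.04, adjusted p = 0.979). Ccl20 rose as given, and Cxcl10, a chemokine induced by interferons, rose from 1295 ± 825 to 3393 ± 1865 (log2 change 1.41 ± 0.18, adjusted p = 0.000709). The neutrophil chemokine Cxcl1 fell from 1330 to 473 (-1.41), Cxcl5 fell as given, the acute phase gene Saa3 fell from 724 ± 222 to 225 ± 56.7 (-1.57 ± 0.23) and the monocyte chemokine Ccl2 fell (-0.86). Without date as a block only Ccl20 of these 6 genes passed (Cxcl10, adjusted p = 0.207; Saa3, 0.056). With 1 array left out, the log2 change of Cxcl10 was 0.73 without untreated replicate 1, 0.83 without LGG replicate 2 and at most 2.10, without untreated replicate 2. Of 27 interferon response genes 2 rose, the antiviral gene Rsad2 (1.21 ± 0.30) and the immunoproteasome subunit gene Psmb8 (0.66 ± 0.18), and 0 fell, the same counts adjusted over the list alone. Neither passed without date as a block (adjusted p = 0.105 and 0.419), and Gbp2 (0.73) and Oasl1 (0.61) did not pass with it. At dates 1 and 2, Psmb8 measured 1060.6 and 2091.5 on the untreated arrays and 1812.2 and 3101.2 on the treated arrays. The interferon list was close to the threshold (median 0.17, camera adjusted p = 0.0495, and 0.669 with an estimated correlation). It lost its call without date as a block (adjusted p = 0.221), under quantile normalization (0.0632) or median scaling (0.0596) and with a filter at 50% of the trimmed mean (0.101). Without untreated replicate 1 its mean was -0.0132 (adjusted p = 0.649) and without LGG replicate 2 its adjusted p was 0.851. Of 11 genes of pattern recognition 0 rose and 0 fell by limma, over all genes or adjusted over the list alone (median 0.01, mean -0.01, adjusted p = 0.943; down by camera and up by fry). They had log2 changes of 0.55 for Tollip, 0.34 for Traf6, -0.48 for Myd88 and -0.34 for Sigirr. Of the antimicrobial genes 2 were tested, too few for a list test, and neither passed; Slpi had a log2 change of -0.42.

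Of 18 targets of NRF2, the regulator of antioxidant genes, 4 rose, 0 fell and 14 did not pass (7 and 0 adjusted over the list alone). The 4 were Gclm (529 ± 88.9 to 1076 ± 225, log2 change 0.99 ± 0.22) and Gclc (0.92 ± 0.25), the subunits of the enzyme that limits glutathione synthesis, Abcc1, an export pump for glutathione conjugates (1.09 ± 0.21), and Osgin1 (1.01 ± 0.27). The list median was 0.25 (adjusted p = 0.00291; adjusted p = 0.669 with an estimated correlation), and without LGG replicate 1 the list lost its call (adjusted p = 0.0578). Hmox1 (0.30), Srxn1 (0.19), Slc7a11 (0.01) and Gsr (-0.04) did not pass. None of the 4 genes that rose passed without date as a block (lowest adjusted p 0.0533, for Abcc1). At dates 1 and 2, Osgin1 measured 115.1 and 57.6 on the untreated arrays and 281 and 129.4 on the treated arrays. Of 4 metallothionein and zinc genes tested, too few for a list test, Mt1 fell from 3087 ± 172 to 714 ± 361 and also passed without the block. Adjusted over the list alone 0 rose and 2 fell. Slc30a1, a zinc exporter gene induced by zinc, measured 144 and 61.9 (log2 change -1.17, adjusted p = 0.0626), Mtf1 0.57 and Slc39a14 0.36, none of which passed. Of 5 genes of the aryl hydrocarbon receptor, which responds to xenobiotics and microbial metabolites, Tiparp (1.39 ± 0.24) and Cyp1b1 (3223 ± 386 to 6539 ± 1922, 0.99 ± 0.15) rose and Ahr itself fell (-1.18 ± 0.21), 3 and 1 adjusted over the list alone. Nqo1 had a log2 change of 0.82 and did not pass (adjusted p = 0.0648). The list did not pass (median 0.82, adjusted p = 0.146), and none of the 3 genes passed without the block.

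Of 19 genes of G2 and mitosis 2 rose, the mitotic kinase gene Aurkb (694 ± 22.9 to 1457 ± 370, log2 change 1.02 ± 0.21) and Top2a, which encodes topoisomerase II alpha (0.69 ± 0.15), and 0 fell, 3 and 0 adjusted over the list alone. Bub1 (0.72, adjusted p = 0.0515) and Prc1 (0.54) did not pass. The list median was 0.41 (adjusted p = 4.47e-05; adjusted p = 0.669 with an estimated correlation). Of 24 genes of the G1 to S transition and replication 1 rose and 3 fell (1 and 4 adjusted over the list alone), with a median of -0.22 (adjusted p = 0.00686; adjusted p = 0.669 with an estimated correlation). The ribonucleotide reductase subunit genes Rrm2 (3036 ± 380 to 1592 ± 158, -0.92 ± 0.18) and Rrm1 (-0.82 ± 0.19) and the helicase gene Mcm7 (-0.58) fell, Cdc45 rose (0.91 ± 0.24) and Pola1 (-0.91) did not pass. The log2 ratios at dates 1 and 2 were uneven for Rrm1 (-1.25 and -0.39) and Cdc45 (0.62 and 1.20). The list lost its call without untreated replicate 2 (adjusted p = 0.0504) and without LGG replicate 2 (0.107), and none of these cell cycle genes passed without date as a block. Of 16 targets of p53, 1 rose and 4 fell (2 and 10 adjusted over the list alone), with a median of -0.49 (adjusted p = 0.000163; adjusted p = 0.669 with an estimated correlation). Zmat3 (2086 ± 8.06 to 877 ± 137, -1.23 ± 0.20), Trp53inp1 (-1.05 ± 0.18), Ccng1 (-1.01 ± 0.16) and Mdm2 (-0.78) fell, while Gadd45a, which is also induced without p53, rose. Gadd45a, Zmat3 and Trp53inp1 passed without the block, and Ccng1 did not (adjusted p = 0.0509). Of 9 genes that restrain apoptosis 0 rose and 0 fell by limma, over all genes or adjusted over the list alone (median 0.08, adjusted p = 0.962). They had log2 changes of -0.52 for Mcl1, 0.49 for Bcl2l2, -0.45 for Birc6 and 0.34 for Bcl2.

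Of 23 genes of glycolysis and the hypoxia response 0 rose, 5 fell and 18 did not pass (3 and 8 adjusted over the list alone), with a median of -0.44, or -0.19 at date 1 and -0.59 at date 2 (adjusted p = 4.01e-05; adjusted p = 0.669 with an estimated correlation). Pdk1, a kinase that holds pyruvate back from mitochondria, fell from 786 ± 241 to 220 ± 66.4 (log2 change -1.72 ± 0.23), Pfkl, the liver form of phosphofructokinase, from 1837 ± 202 to 786 ± 1.20 (-1.19 ± 0.20) and the glucose transporter gene Slc2a1 from 881 ± 168 to 393 ± 115 (-1.13 ± 0.22). Ldha (-0.77) and Bnip3 (-0.83) also fell, whereas Hk2 (-0.97, adjusted p = 0.0569), Pfkp (0.80) and Hk1 (0.72) did not pass. Pdk1 and Pfkl passed without date as a block, and Slc2a1 did not (adjusted p = 0.0988). Of 63 genes of oxidative phosphorylation 0 rose and 0 fell by limma, over all genes or adjusted over the list alone (median 0.03, adjusted p = 0.865). The members with the largest changes, Ndufaf1 (0.60), Cox6a2 (0.58), Ndufaf5 (0.54) and Ndufa9 (-0.48), did not pass. Of 17 genes of cholesterol synthesis 2 rose, Dhcr7, the last enzyme of the pathway (339 ± 38.2 to 1124 ± 134, 1.66 ± 0.22), and Msmo1 (0.98 ± 0.19), and 0 fell, 3 and 0 adjusted over the list alone. The list did not pass (median 0.19, adjusted p = 0.106), nor did Cyp51 (0.67) or Mvk (-0.61). Without the block Dhcr7 passed and Msmo1 did not (adjusted p = 0.177). Of 12 genes of fatty acid synthesis 0 rose and 1 fell, the desaturase gene Fads2 (-0.88 ± 0.19; without the block, adjusted p = 0.177), 0 and 2 adjusted over the list alone (median -0.05, adjusted p = 0.38). Me1 (0.59), Srebf1 (-0.51) and Scd2 (-0.46) did not pass. Of 36 proteasome genes 2 rose, Psmd8 (0.84 ± 0.16) and Psmb8, which belongs to the immunoproteasome, and 0 fell, 1 and 0 adjusted over the list alone (median 0.12, adjusted p = 0.146). Psmb10 (0.67) and Psmd5 (0.65) did not pass. Of 36 ribosomal protein genes 0 rose and 1 fell, over all genes or adjusted over the list alone: Rpl7l1, a paralog of Rpl7 (-1.08 ± 0.23). That list did not pass (median 0.10, adjusted p = 0.262), and Rpl8 (0.43), Rpl39 (-0.31) and Rps27l (-0.26) did not pass. Without the block none of Psmd8, Psmb8 and Rpl7l1 passed.

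Levels of cell type markers ranged widely within the lists, and levels of different probe sets are not directly comparable. In untreated cells the mesenchymal and matrix genes Sparc, Vim and Col1a1 measured 14064 ± 2565, 11394 ± 1547 and 8362 ± 2537, whereas Lum, Thy1 and Pdgfrb measured 74.5, 78.0 and 55.3. Of the junction and keratin genes, F11r measured 2258 ± 401, Tjp1 1620.3 ± 154, Krt18 1077 ± 342 and Krt8 542 ± 157, whereas Cdh1 measured 25.3 ± 23.4 and Epcam 6.5 ± 0.707. The enterocyte gene Vil1 measured 4.6 ± 3.54. After treatment Cdh1 measured 22.8 ± 4.60 and Epcam 8.75 ± 0.354. Above the filter were 19 of 22 mesenchymal and matrix genes, 7 of 19 junction genes, 5 of 10 goblet genes, 4 of 13 leukocyte genes and 0 of 15 enterocyte genes. The markers thus do not by themselves show an epithelial character, although some keratin and junction genes were well above the filter. The identity of the cells was not tested. Of the 19 mesenchymal and matrix genes 0 rose and 4 fell (1 and 6 adjusted over the list alone), with a median of -0.22 (adjusted p = 0.000924; adjusted p = 0.669 with an estimated correlation). Col6a1 (7996 ± 2.83 to 3841 ± 1.77, log2 change -1.05 ± 0.13) and Col6a2 (-0.78 ± 0.14), which encode collagen VI chains, the proteoglycan gene Dcn (8055 ± 454 to 4279 ± 275, -0.91 ± 0.13) and Lox (-0.48) fell. Loxl1 (-0.65) did not pass, and Col1a1 (-0.04) and Fn1 (-0.06) had adjusted p of 0.902 and 0.813. Col6a1 and Dcn passed without date as a block. Of the 7 junction genes 0 rose and 1 fell, the claudin gene Cldn15 (511 ± 148 to 171 ± 41.4, -1.43 ± 0.28; without the block, adjusted p = 0.065), 1 and 2 adjusted over the list alone (median -0.30, adjusted p = 0.0813). Krt19 (-0.72), Krt18 (0.66) and Jup (-0.51) did not pass. Of the 5 goblet genes 0 rose and 1 fell, Klf4, a transcription factor gene (-0.96 ± 0.25; without the block, adjusted p = 0.347), 1 and 1 adjusted over the list alone (median -0.10, adjusted p = 0.712). The log2 change of Klf4 was -1.69 without LGG replicate 1 and -0.23 without LGG replicate 2. Fcgbp (0.95), Atoh1 (-0.45) and Muc13 (0.17) did not pass. Of the 4 leukocyte genes above the filter, too few for a list test, Cd68, which encodes a lysosomal protein, rose from 124 ± 31.7 to 282 ± 10.5 (1.06 ± 0.27; without the block, adjusted p = 0.109), with 1 and 0 adjusted over the list alone. The list had a median of -0.03 and a mean of 0.22. Ptprc, the pan-leukocyte marker, measured 26.3 ± 15.4 and 21.4 ± 2.62.

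Targets of SRF and YAP, which follow the state of the actin cytoskeleton, included 3 that rose and 1 that fell of 14 tested, the same counts adjusted over the list alone. Ccn2 rose from 2437 ± 837 to 8174 ± 111, Ccn1 from 3918 ± 508 to 8823 ± 643 (log2 change 1.17 ± 0.13) and Ankrd1 by a log2 change of 1.24 ± 0.27, while the tropomyosin gene Tpm1 fell (-0.68 ± 0.17). The list did not pass (median 0.04, adjusted p = 0.211), and Ccn2 and Ccn1 passed without date as a block. Of 11 targets of TGF-beta 1 rose, Ccn2, and 1 fell, Id1, an inhibitor of differentiation (2110 ± 113 to 769 ± 443, -1.55 ± 0.27; without the block, adjusted p = 0.0867), 2 and 1 adjusted over the list alone (median -0.22, mean -0.06, adjusted p = 0.687; down by camera and up by fry). The log2 change of Id1 was -2.15 without LGG replicate 1 and -0.95 without LGG replicate 2. Tgfb1 (0.77) and Pmepa1 (-0.62) did not pass. Of 6 Wnt targets 0 rose and 0 fell by limma, over all genes or adjusted over the list alone (median 0.07, adjusted p = 0.738). They had log2 changes of 0.55 for Cd44, 0.35 for Notum and -0.28 for Ccnd1.

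In all, 10 of 25 lists passed camera with the preset correlation. With a correlation estimated from the residuals, limma's camera passed 0 lists (0 at an unadjusted p under 0.05). The residuals have 1 degree of freedom, so this form could hardly pass any list and its 0 decides nothing. The preset correlation is an assumption that these arrays do not test. Limma's fry, which tests whether a list's genes move on balance one way, passed 0 (3 at an unadjusted p under 0.05, lowest adjusted p 0.0826, for the p53 targets).

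The comparison of the dates asks how far the response was the same when each date was taken alone. Across the 6952 genes, the log2 ratios of the dates correlated with a Pearson r of 0.55 and a Spearman rho of 0.48, and 65.2% of genes had the same sign, a description across genes, which are not independent replicates. At date 1 alone 151 genes were at least 2-fold higher and 158 at least 2-fold lower, and at date 2 alone 199 and 221. Ccl20 (2.17 and 3.73), Arrdc4 (1.97 and 2.48) and Igfbp3 changed more at date 2, whereas Hspa1a, Ppp1r15a (2.36 and 0.72) and Atf3 (2.30 and 0.37) changed more at date 1, and Col6a1 changed by -1.05 at each. Whether the response of any gene differed between the dates was not tested, since 1 array per group and date leaves no residual degrees of freedom for it.

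**Figure D3:**
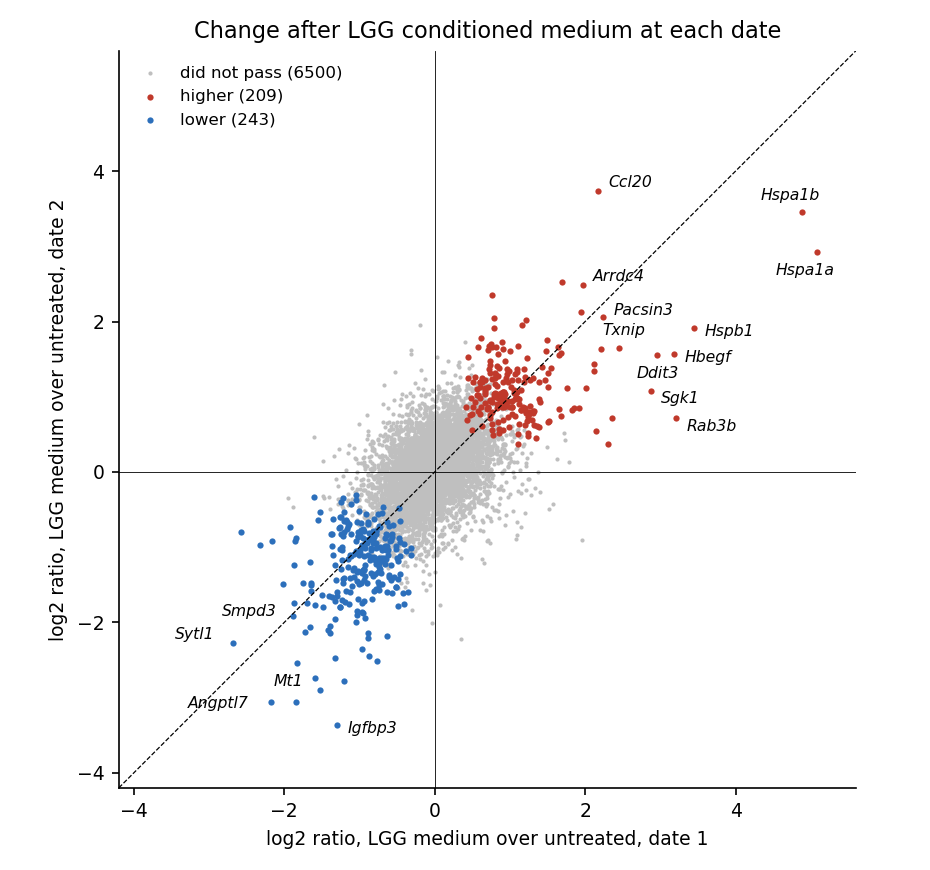
Log2 ratio of LGG conditioned medium over untreated cells at date 1 (x axis) and at date 2 (y axis) for each of 6952 genes, with red points for the 209 genes that rose, blue points for the 243 that fell, grey points for genes that did not pass and a dashed line where the dates are equal. Hspa1a, Hspa1b and Hspb1 lie far to the right and under the line, and Ccl20 lies above it.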

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

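All tests in this part were chosen after the result was seen, and none compares replicates, since each date holds 1 array per group.

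The probe sets without values at date 1 gave a signal at date 2 that the comparison of the groups does not use. Of 1046 genes measured above the filter at date 2 alone, 36 were at least 2-fold higher and 32 at least 2-fold lower on the treated array than on the untreated one. Zfp688 was 6.15-fold higher and Cystm1 3.62-fold higher, and Dido1 was 8.46-fold lower and Trio 3.65-fold lower. Zfp688 measured 26.5 untreated, near the pseudocount of 25.2, and 292.9 treated. Mt2, the second metallothionein gene of its list, measured 2760 untreated and 790 treated, 3.42-fold lower. These values have no replicate. Of the 6952 genes tested with values at both dates, 420 were at least 2-fold changed at date 2. Of these 420, 386 (91.9%) moved the same way at date 1 by any amount, against 65.2% of all genes tested. Only 47 genes were at least 2-fold higher and 71 at least 2-fold lower at both dates, so most of the 420 were not 2-fold changed at date 1. Of the 420, 265 (63.1%) were called, although date 2 itself entered those calls. Of the 33 that were at least 4-fold changed at date 2, 32 moved the same way at date 1, again by any amount.

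A control probe set for the murine B2 repeat, a short interspersed element carried in many transcripts, stood out among the control probe sets, which enter no comparison. Its ratio of treated to untreated was 2.66 at date 1 (562.5 to 1499) and 1.23 at date 2, with ratios of 1.72 and 1.15 for a B1 repeat and 1.08 and 1.22 for another B2 probe set. The scaling or hybridisation of the treated array of date 1 would raise the bacterial controls added to each sample as much. Their 18 ratios at date 1 had a median of 1.19 and a highest value of 1.60, so an effect shared by the whole array is argued against as the whole cause. The probe set was picked for its high ratio, so noise of a single probe set is not excluded. Unspliced transcripts or genomic DNA that carry the repeat remain possible, since no probe set is marked as intronic or genomic to set against the log2 ratio of 1.41. A response of the repeat to the treatment stays open too, although the other, brighter B2 probe set went only from 13832 to 14906 at date 1.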

How the results depend on the processing

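The settings for probe sets that bind several transcripts, the Rps6k kinases and the correlation of the dates were chosen after the data were seen. Without probe sets that can bind several transcripts, 369 of 6725 genes passed (limma), of which 367 were among the 452. Of the 73 named genes that had passed and were still measured, 70 kept their call and 3 lost it. Without date as a block the counts of higher and lower genes went from 209 and 243 to 24 and 37. With no filter both were 0 (limma; 1525 genes at an unadjusted p under 0.05), and prior degrees of freedom went from 12.5 to 5.01. Without a trend in eBayes they were 115 and 129, of which 241 were among the 452. Median scaling gave 154 lower genes, an adjusted p under 0.10 gave 334 higher and probe sets in place of genes gave 399 lower. Leaving out 1 array at a time without the block gave 0 to 198 higher and 0 to 230 lower genes: 0 and 0 without either untreated array (485 and 533 genes at an unadjusted p under 0.05, against 1064 with all arrays and no block), 198 and 230 without LGG replicate 1, and 74 and 113 without LGG replicate 2. A lone array was assumed to vary like the other group. The counts of genes 2-fold changed at both dates went from 47 and 71 to 28 and 45 with a pseudocount of 20%, and to 258 and 275 at 1.5-fold, with 27 in opposite directions. The correlation of the dates was 0.39 with no filter and 0.59 with a filter at 50%. An estimated correlation and fry each passed 0 of 25 lists (limma, 0 and 3 at an unadjusted p under 0.05). The first could hardly pass any, with 1 residual degree of freedom.

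Among the genes named by rule and the 10 lists that passed, a direction reversed in 4 cases, each without 1 array. Other genes in the text were not refitted with an array left out, so the count does not cover them. With 1 array left out the mean of the interferon list lay between -0.0132 (without untreated replicate 1) and 0.415, and that of the immediate early list between -0.00365 (without LGG replicate 1) and 0.949. The log2 change of Gbp2 lay between -0.0766 (without LGG replicate 2) and 1.54, and that of Rps27l between -0.581 and 0.0529 (without LGG replicate 2). For these and the other changes given, the cause was not tested. Of the 75 named genes that passed, 32 kept their call without the block, 72 with a pseudocount of 1%, 75 with 20%, 71 with quantile normalization, 68 with median scaling and 59 of 62 with a filter at 50%; none turned under these settings, and 0, 0, 55 and 54 kept it without untreated replicate 1, untreated replicate 2, LGG replicate 1 and LGG replicate 2. Of the 10 lists, 9 kept their call without the block, the interferon list being lost. That list was also lost with quantile normalization, with median scaling and with a filter at 50%. Brightness limits dim genes: values near the pseudocount of 25.2 say little about fold.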

Other observations

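The tests of the dates and of the scaling in this part were chosen after the results were seen, and the count over other groupings of the arrays was planned.

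Some called genes outside the lists and the rule for named genes were chosen for description after their values were seen. Dnaja4, a co-chaperone of Hsp70 that was in no list, rose from 235 ± 22.7 to 733 ± 22.1 (SD, n = 2), a log2 change of 1.54 ± 0.23 (SE; limma, adjusted p = 0.00174). Fgf21, a secreted target of ATF4, rose from 90.6 ± 50.7 to 330 ± 141 (1.63 ± 0.26, adjusted p = 0.00272), and Socs2, a suppressor of cytokine signalling, from 49.1 ± 12.4 to 202 ± 48.4 (1.61 ± 0.28). Gas5, a growth arrest RNA that hosts small nucleolar RNAs, rose from 1874 ± 164 to 5009 ± 955 (1.40 ± 0.18), and Gas1, a membrane protein of growth-arrested cells, fell from 5729 ± 101 to 2142 ± 512 (-1.43 ± 0.17). All 5 also passed under quantile normalization and median scaling, and Dnaja4, Gas5 and Gas1 passed without date as a block, whereas Fgf21 (adjusted p = 0.102) and Socs2 (0.0517) did not.

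Genes of the major histocompatibility complex with an H2 symbol, a set chosen after H2-Q5 was seen, gave 2 that rose and 0 that fell of 11 tested, under the deposited scaling, quantile normalization and median scaling alike. H2-Q5 rose from 96.7 ± 12.9 to 532 ± 274 and H2-Ab1 had a log2 change of 1.44 ± 0.27. The values of H2-Ab1 differed by date on the untreated arrays (SD 165 on a mean of 151) and on the treated arrays (SD 308 on a mean of 394). Without date as a block H2-Ab1 did not pass (limma, adjusted p = 0.404), and it was not refitted with an array left out. The median of the 11 was 0.46, and H2-K1 (0.31) and H2-D1 (0.29) did not pass.

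The heat shock, immediate early and integrated stress genes that rose mostly had larger changes at date 1 (15 of 17, with a median gap of 0.82 on the log2 scale). The treated array of date 1 also stood apart in other ways: the 3' to 5' ratio of Gapdh went from 0.805 to 0.931 and that of actin from 1.11 to 1.20 with treatment at date 1, against 0.784 to 0.768 and 1.08 to 1.05 at date 2. A probe set for the B2 repeat had its ratio of 2.66 at date 1, against 1.08 for the other B2 probe set. The gap is that of members chosen because they rose: over all members tested, the medians at dates 1 and 2 were 0.54 and 0.25 for the heat shock list and 0.78 and -0.07 for the immediate early list, but 0.43 and 0.42 for the integrated stress list. Larger changes in general at date 1 were not seen on these arrays. The median gap of the 434 called genes outside these lists was -0.167 (bootstrap 95% interval -0.224 to -0.115). It was -0.125 for the 192 that rose and -0.241 for the 242 that fell. A lower starting level was not seen either, since the untreated arrays differed in the 17 genes by a median of -0.000494 (-0.0633 to 0.0563). Both intervals resample genes and not arrays, so they say nothing of another pair of arrays. The fit that called the 434 genes also favours genes with a small gap. A different exposure or culture at the 2 dates may be the source, as may a stronger batch of conditioned medium or the RNA of that array, whose quality was not tested as a source, and with 1 array per group and date they cannot be told apart.

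Txnip and Arrdc4, known targets of the glucose sensor MondoA, rose while the glycolysis and hypoxia list had a median under 0. Under quantile normalization and median scaling the mean of the list stayed at least 0.436 below the median of all genes (-0.436 at the closest). Median scaling moves all genes of an array nearly alike, so that part of the test could not have come out otherwise. Quantile normalization can move bright and dim genes apart, so only a scaling error of that kind is argued against. RNA degradation is argued against as the whole cause, since the list median was -0.591 at date 2, where the 3' to 5' ratio of Gapdh changed by -0.0168 with treatment. Acid, lactate or depleted nutrients in the conditioned medium may give the same pattern as a signal from the bacteria, and no array of cells given such medium without LGG was analysed here, so the log2 change of 2.05 of Txnip cannot be assigned to either.

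The 4 arrays can be grouped 2 against 2 in 3 ways, too few for a share under 0.05. Without a date term the real grouping called 61 genes, the highest other grouping called 0, and 1 of the 3 groupings gave as many as the real one, which is the real one itself. In the other groupings each side held 1 treated and 1 untreated array, so any effect of treatment added to their residual. Their counts would then be low in any case, and the contrast with 61 decides nothing.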
